A study of Homo sapiens with 6 samples.

How the data were processed

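KG1a cells were profiled as 3 control samples and 3 samples exposed to 10 µM MCL for 8 h, per the labels, each on 1 array of an Agilent 1-colour whole human genome design. The deposited scanner files hold spot intensity values that Agilent Feature Extraction made from the images, per the file headers, with background subtraction, spatial and multiplicative detrending and surrogate values for dim spots, and with no normalization between arrays. The submitters' processing notes give Feature Extraction 9.1, while the file headers give version 10.7.3.1. The authors also deposited a value table on the log2 scale. Its columns followed log2 of the processed signal of the same array with r above 0.999, all had a median of 7.39, and their sorted values differed by at most 0.0053, as after quantile normalization. Its scale and direction were thus settled from the values, and the tool that made it is not given in the sources used here.

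From the deposited intensities, log2 of the processed signal was taken and the 75th percentile of each array was subtracted, which stood at signals of 1440 to 1818. This scaling assumes that bright transcripts as a whole do not change. Control spots and spots with outlier flags were left out, and spots of one probe were averaged on the log2 scale. Of 41000 probes, 47 had no unflagged value on some array and were left out. Probes were kept when well above background on all arrays of at least 1 group, which left 26839. Probes were named through their transcript accession (27197 probes), a current symbol (2338) or an older symbol (454) in a RefSeq gene table of GRCh38.p14, which was used for names only. For 95 probes the file's name was kept, and 10916 had no gene name. Of the kept probes 5698 were unnamed and took no part in the gene counts. Each gene was represented by its brightest kept probe, which gave 13484 genes. Among 5473 genes with several kept probes, 16 had probes called in opposite directions, none of them among the 42 named genes with several probes. Probe positions are those of the files, in hg19 coordinates, and exons or untranslated regions were not analysed here.

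Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (both directions tested) with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior degrees of freedom were 3.16 beside 4 residual ones. The number of arrays limits the precision, and an exact permutation of 3 against 3 samples could not give a p under 0.1. Before the data were examined, 27 gene lists, the design and the alternatives were fixed. Lists were tested with camera of limma (preset correlation 0.01), also with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes.

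The named genes were also fixed by rule in advance. They are the 12 highest and 12 lowest called genes that were above background on all 6 arrays with no overlap between groups, up to 4 genes each way seen above background in 1 group only, up to 4 genes per list with the largest changes among those called and above background on all 6 arrays, and 5 genes by name (MCL1, NFKBIA, HMOX1, CD34 and MYC). HMOX1 is named under several parts of the rule.

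The alternatives were normexp background correction (offset 50), quantile normalization, the 75th percentile over detected probes or the median for scaling, other filters on dim probes, the mean of a gene's probes, the authors' value table, the slide as a fixed or random block, slide 1 alone, a replicate block, a trended robust variance, array weights, leaving out each array, and a threshold of 0.01. The fit and the list test were tested on simulated data with the real means and spreads of the 13484 genes and 200 changed genes for MCL against control. At log2 sizes of 0.3, 0.6, 1 and 2, 10%, 86%, 96% and 96% of 50 changed genes each were recovered, with 7 false calls among 151, and a planted list of 30 genes shifted by 0.3 passed while none of 27 unchanged lists did. Of 20 simulations with no changed gene 3 gave called genes and none gave a list. In that simulation genes varied independently of each other. Figures were drawn with matplotlib in Python.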

Results

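Gene expression was measured in KG1a cells, an established human acute myeloid leukaemia line with an immature phenotype, with and without an agent that the labels call MCL and do not spell out. The labels put 3 arrays in the control group and 3 in the MCL group, and give an exposure of 10 µM for 8 h. Total RNA of each sample was labelled with Cy3 and hybridised alone to an Agilent whole human genome array, so each array gives 1 fluorescence signal per spot. Of the 43376 spots that are not controls, between 28523 and 31084 per array (65.8% to 71.7%) were well above background, and none was saturated. After filtering, 13484 named genes were compared. All 3 control arrays and MCL replicate 1 were on slide 1, and MCL replicates 2 and 3 were on slide 2, so the calls lost with the slide as a block are given for each gene group, and values within slide 1 for the main counts, the top genes and several lists. Within slide 1 the spread comes from the 3 control arrays alone, and the lone MCL array is assumed to vary like them. Signals are given as log2 values relative to the 75th percentile of the array, the SE is that of the limma fit, and n = 3 per group throughout unless stated otherwise.

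The comparison asks which transcripts differ between KG1a cells exposed to MCL and control cells. Genes of the antioxidant response driven by the transcription factor NRF2 and of the amino acid and stress response driven by ATF4 rose as lists in camera with its preset correlation, led by HMOX1, which was 48.2-fold higher. Neither list passed with an estimated correlation (adjusted p = 0.068 for each), while both passed in fry (adjusted p = 0.00019 and 0.00067). The lists of replication-dependent histone, DNA replication, ribosome biogenesis and interferon-stimulated genes and of lymphoid markers fell by smaller amounts in camera with its preset correlation. For these the adjusted p was 0.47, 0.47, 0.33, 0.19 and 0.19 with an estimated correlation, and 26 of the 45 DNA replication genes did not pass. In fry these lists passed (adjusted p from 0.0012 to 0.017). In limma, 3494 genes (25.9% of those tested) passed an adjusted p of 0.05, 1334 of them higher and 2160 lower with MCL. Of these, 161 also differed at least 2-fold, 74 higher and 87 lower. The share of the called genes that were higher depended on the scaling: it was 38.2% here, 48.2% after quantile normalization and 48.5% in the authors' value table. With the slide as a block 588 genes passed, 294 each way, and within slide 1 (3 control arrays against 1 MCL array, whose own spread is not measured) 459 passed, 223 higher and 236 lower. All 3494 called genes had the same sign in those fits, and 555 of the 588 genes were among them. The shared sign was nearly fixed in advance, since 3492 of the 3494 had all MCL values on one side of all control values. Both fits also take the change from MCL replicate 1 against the 3 control arrays, which are part of the main comparison. With normexp 120 of the 3494 had the opposite sign, and with the mean of a gene's probes 23 had.

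Among called genes above background on all 6 arrays with no overlap between groups, HMOX1 and OSGIN1 led the 12 highest changes. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1 (probe on chromosome 22, 35790122 to 35790181, hg19), went from 0.01 ± 0.36 (SD) in control to 5.60 ± 0.18 (SD) with MCL, a log2 change of 5.59 ± 0.18 (SE, limma adjusted p = 5.2e-05). OSGIN1, an oxidative stress-induced growth inhibitor (chromosome 16, 83999149 to 83999208), went from -2.44 ± 0.16 (SD) to 0.66 ± 0.07 (SD), a change of 3.103 ± 0.092 (SE). NQO1, a quinone reductase, was 4.90-fold higher, SLC7A11, the cystine transporter subunit, 4.67-fold and SRXN1, which restores oxidised peroxiredoxins, 3.63-fold. Further genes in this top group were VEGFC, a lymphatic growth factor (5.59-fold), CLEC1B, a platelet receptor (5.07-fold), ADM, the vasodilator peptide adrenomedullin (4.68-fold), and FTMT, mitochondrial ferritin (4.18-fold). VEGFC, CLEC1B and FTMT were dim in control (means of -4.79, -4.88 and -4.91), so their folds rest on low signals. MIR155HG, the host gene of a microRNA, was 3.43-fold higher, DNAJB4, a heat shock co-chaperone, 3.38-fold, and HBD, the delta globin chain, 3.36-fold. All 12 passed in limma, with adjusted p from 5.1e-05 to 0.0081. FTMT no longer passed with the slide as a block (limma adjusted p = 0.11), and within slide 1 VEGFC did not (adjusted p = 0.079). With normexp background correction CLEC1B (adjusted p = 0.086) and FTMT (adjusted p = 0.15) did not pass.

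CTSH and TRANK1 led the 12 lowest changes among called genes above background on all 6 arrays with no overlap between groups. CTSH, the lysosomal protease cathepsin H (chromosome 15, 79214209 to 79214268, hg19), went from -1.07 ± 0.04 (SD) in control to -2.84 ± 0.21 (SD) with MCL, a log2 change of -1.77 ± 0.11 (SE, limma adjusted p = 0.00035). ZAP70, a kinase of T-cell receptor signalling (chromosome 2, 98356255 to 98356314), changed by -1.48 ± 0.13 (SE, adjusted p = 0.00096). IKZF2, the Ikaros family factor Helios, changed by -1.34 ± 0.09 (SE) from a control level of 2.70, the brightest of the 12 probes. IL1RL1, the interleukin-33 receptor, was 2.63-fold lower, and CD200R1, an inhibitory receptor of leukocytes, also 2.63-fold. TRANK1 (3.098-fold), RTN4R (2.86-fold), SLC30A3, a zinc transporter (2.80-fold), KIRREL3 (2.72-fold), PHLDA1 (2.61-fold), MEI1 (2.58-fold) and the olfactory receptor gene OR4A15 (2.49-fold) completed the set, with limma adjusted p from 0.00027 to 0.040 over the 12 genes. TRANK1, CD200R1, SLC30A3, KIRREL3 and OR4A15 were dim with MCL (means from -4.82 to -5.42), so their folds rest on low signals. MEI1 had a further kept probe that was not called (-0.25), and 2 of 3 IKZF2 probes were called. SLC30A3 (adjusted p = 0.079), KIRREL3 (0.063) and OR4A15 (0.084) did not pass with the slide as a block. Within slide 1 CD200R1 (adjusted p = 0.067) and OR4A15 (0.13) did not, and with normexp background correction CD200R1 (0.070) and OR4A15 (0.087) did not. OR4A15 also did not pass after quantile normalization, in the authors' value table, without the filter on dim probes, or without control replicate 1 or 3 or any MCL replicate (adjusted p from 0.012 to 0.13 over its alternatives).

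**Figure D1:**
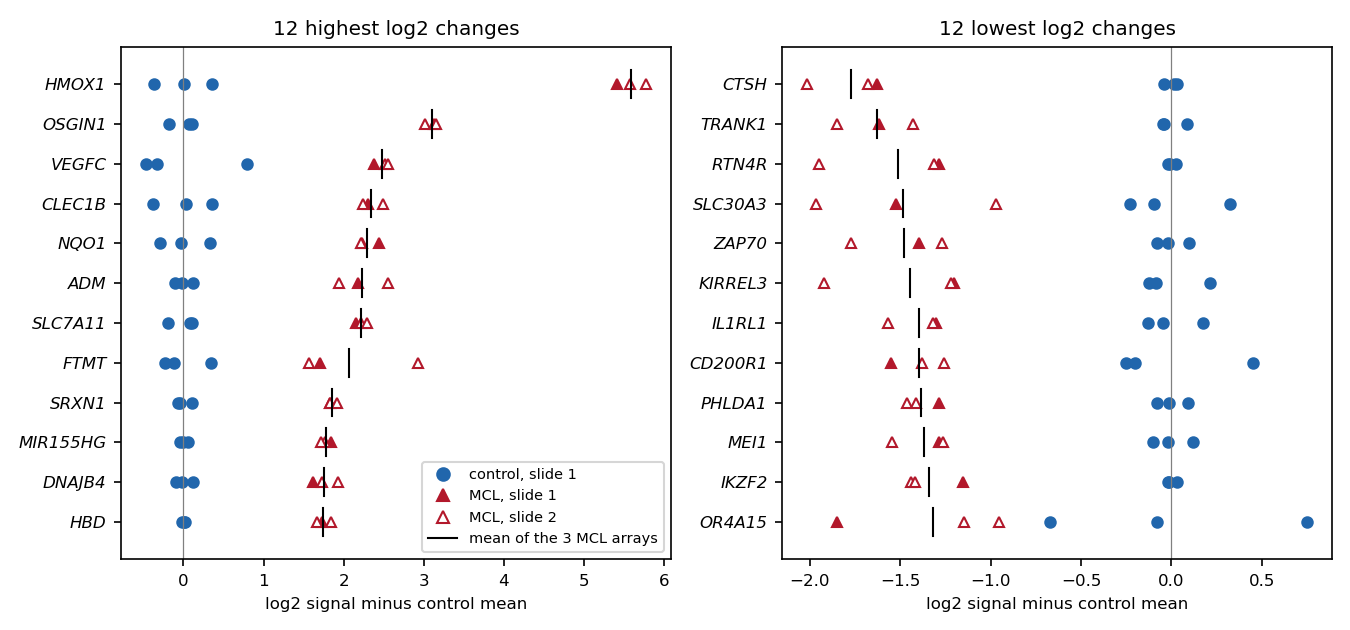
Log2 signal of each array minus the control mean (x axis) for the 12 genes with the highest and the 12 with the lowest log2 change among called genes above background on all 6 arrays (y axis); circles are control arrays, triangles MCL arrays, filled on slide 1 and open on slide 2, and the black line is the mean of the 3 MCL arrays. The 3 MCL arrays lie on one side of all 3 control arrays for each gene, which the rule that chose these genes required. HMOX1 stands apart with a mean change of 5.59.

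Some genes had a probe well above background on every array of one group and on none of the other, which gives only a lower bound of the fold. The bound sets the mean of the brighter group against the dimmer group's own signals, raised on each array to at least the lowest signal found among probes well above background. IBSP, which encodes bone sialoprotein, was at least 3.05-fold higher with MCL (limma adjusted p = 0.012), THRSP at least 2.12-fold (0.041), PPP1R36 at least 1.80-fold (0.00078) and AMBP at least 1.68-fold (0.039). PARP15 was at least 4.35-fold lower with MCL (adjusted p = 0.0041), ANKRD22 at least 3.103-fold (0.039), the interferon-induced chemokine gene CXCL10 at least 2.36-fold (0.00012) and IKZF3, the Ikaros family factor Aiolos, at least 2.14-fold (0.0010). PPP1R36, PARP15, CXCL10 and IKZF3 passed in limma with the slide as a block, while IBSP (adjusted p = 0.072), THRSP (0.41), AMBP (0.28) and ANKRD22 (0.22) did not. Within slide 1 IBSP passed (adjusted p = 0.041), while THRSP (0.092), AMBP (0.32), ANKRD22 (0.23) and PARP15 (0.082) did not. Several bounds rest on single arrays. The bound of IBSP was 1.84-fold without MCL replicate 2 and 5.42-fold without MCL replicate 1, and that of THRSP 1.34-fold and 3.26-fold. The bound of PARP15 was 2.85-fold without control replicate 3 and 7.13-fold without control replicate 2, and that of ANKRD22 1.76-fold without control replicate 2. The log2 change of THRSP with the slide as a block, 0.75, lay below its bound over all 6 arrays (1.09). With normexp PPP1R36 (-0.14) and AMBP (-0.0897) turned to lower log2 signals with MCL, neither past the threshold, so their direction depends on the background correction. With normexp only PARP15 of these 8 genes passed (adjusted p = 0.039), and without the filter on dim probes IBSP, THRSP, AMBP and ANKRD22 did not pass.

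Of 29 tested genes of the NRF2 and glutathione-thioredoxin list, 22 rose and 1 fell, and 22 rose and 2 fell when adjusted over the list alone. The median log2 change was 0.52. Of 29 ATF4 and integrated stress response genes 24 rose and none fell, the same counts as when adjusted over the list alone, with a median of 0.54. This list was led by JDP2, a repressor of AP-1 (1.59 ± 0.19, SE), the serine synthesis enzymes PSAT1 (1.46 ± 0.09) and PHGDH (1.28 ± 0.08), and ASNS, asparagine synthetase (1.43 ± 0.12). Camera, limma's test of a list against all other genes, gave an adjusted p of 4.2e-16 for both lists with its preset correlation, and 1.1e-16 with the slide as a block. With an estimated correlation neither list passed (adjusted p = 0.068 for each). In limma 14 of the NRF2 genes and 13 of the ATF4 genes rose with the slide as a block.

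Smaller rises were seen in 5 other lists. Of 29 autophagy and lysosome genes 9 rose and 1 fell (the same when adjusted over the list alone), among them the cargo receptor SQSTM1 (1.21 ± 0.06, SE), which is also on the NRF2 list, GABARAPL1 (1.01 ± 0.12), the transcription factor TFE3 (0.66 ± 0.08) and MAP1LC3B (0.55 ± 0.07). The list's camera adjusted p was 7.8e-06, with adjusted p = 0.068 with an estimated correlation. Of 28 heat shock and chaperone genes 8 rose and 1 fell (the same when adjusted over the list alone), with DNAJB2 (0.50 ± 0.06) and HSPH1 (0.42 ± 0.11) higher and CRYAB (-0.48 ± 0.13) lower. The list passed in camera (adjusted p = 0.0072), but not with the slide as a block (adjusted p = 0.05002) or with an estimated correlation (adjusted p = 0.29), and within slide 1 its adjusted p was 0.049. Of 35 proteasome genes 5 rose and none fell, and none passed when adjusted over the list alone, with PSMD11 at 0.41 ± 0.09 (SE). The camera adjusted p was 0.0011, and the adjusted p was 0.19 with an estimated correlation. Of 16 hypoxia-inducible genes 4 rose (4 adjusted over the list alone), ADM and the growth factor gene VEGFA (0.71 ± 0.19) among them. Its camera adjusted p was 0.0090, but 0.055 with the slide as a block, 0.049 within slide 1 and 0.24 with an estimated correlation. Of 44 G2/M and mitosis genes 13 rose and 4 fell (the same when adjusted over the list alone), with the phosphatase gene CDC25B (0.68 ± 0.13), HMMR (0.60 ± 0.09) and KIF14 (0.53 ± 0.07) higher and the kinase gene PBK lower (-0.63 ± 0.06). The camera adjusted p was 0.00018, and the adjusted p was 0.19 with an estimated correlation. In limma with the slide as a block 5 autophagy, 2 heat shock, 1 hypoxia-inducible and no proteasome genes rose, and 1 G2/M gene rose and 1 fell. Of the genes named here DNAJB2, HSPH1, CRYAB, PSMD11, VEGFA, CDC25B and HMMR did not pass with that block (adjusted p from 0.053 to 0.36).

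Of 34 replication-dependent histone genes 22 fell and 1 rose (28 and 2 adjusted over the list alone), with a median of -0.36 and with H1-3 (-1.20 ± 0.11, SE), H2AC16 (-0.90 ± 0.15) and H2BC5 (-0.81 ± 0.06) lowest on the probes used. The other H2BC5 probe was at -0.27 and was not called. The size of the histone fall depended on the control array. Relative to all genes, the median for MCL replicate 1 was -0.42 against control replicate 2, but -0.16 and -0.18 against control replicates 1 and 3. Of 45 G1/S and DNA replication genes 19 fell and none rose (21 and none adjusted over the list alone), including the replicative helicase subunits MCM2 (-0.60 ± 0.13) and MCM7 (-0.57 ± 0.10), the sliding clamp PCNA (-0.51 ± 0.06) and CDC45 (-0.46 ± 0.09). Of 43 MYC and ribosome biogenesis genes 23 fell and 2 rose (28 and 2 adjusted over the list alone), with IMP4 (-0.68 ± 0.07) and NOLC1 (-0.60 ± 0.09) lower and MXD1, an antagonist of MYC, higher (0.54 ± 0.07), as was MYCN, named after its value was seen (0.33 ± 0.09). Of 61 cytosolic ribosomal protein genes 11 fell and none rose, but none passed when adjusted over the list alone, and the median was -0.18, but -0.065 after quantile normalization, -0.068 in the authors' value table, -0.12 with normexp and -0.27 within slide 1. Camera gave adjusted p = 5.2e-06 for the histone and the ribosome biogenesis lists, 0.0018 for the G1/S list and 0.00022 for the ribosomal proteins. The adjusted p was 0.47, 0.33, 0.47 and 0.61 with an estimated correlation, in that order. With the slide as a block the G1/S list did not pass (adjusted p = 0.065), nor did it within slide 1 (0.069), while the histone (0.00011), ribosome biogenesis (0.00027) and ribosomal protein (7.2e-09) lists passed. In limma with that block 2 histone genes, 1 G1/S gene and 1 ribosome biogenesis gene fell, 1 ribosome biogenesis gene rose, and no ribosomal protein gene passed, while H2AC16, MCM2, MCM7, CDC45, NOLC1 and MYCN lost their calls (adjusted p from 0.073 to 0.22). The ribosomal protein list did not pass after quantile normalization (adjusted p = 0.085), in the authors' value table (0.059) or with normexp (0.14).

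Of 30 interferon-stimulated genes 17 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.33. The antiviral genes OAS3 (-1.04 ± 0.11, SE), IFI44L (-0.998 ± 0.201), MX1 (-0.97 ± 0.08) and IFIT1 (-0.67 ± 0.08) changed most among those above background on all 6 arrays. Of 21 tested lymphoid cell markers 12 fell and none rose (15 and none adjusted over the list alone), with a median of -0.39. Among them were NCAM1 (-0.94 ± 0.12), TRAT1 (-0.84 ± 0.09), the T-cell receptor chain CD3D (-0.79 ± 0.06, from a control level of 3.63) and perforin, PRF1 (-0.60 ± 0.09). Camera gave adjusted p = 3.4e-05 for the interferon list and 9.0e-05 for the lymphoid list. The adjusted p was 0.19 for each with an estimated correlation. With the slide as a block both lists passed in camera (adjusted p = 0.00016 and 0.00011), and 7 interferon-stimulated genes and 4 lymphoid markers fell in limma. NF-kB target genes were at the threshold as a list: camera gave an adjusted p of 0.051, 10 of the alternatives that kept its preset correlation gave 0.023 to 0.050, and fry gave 0.0012. The others of these alternatives did not pass, nor did the list with an estimated correlation (adjusted p = 0.24). Of 30 such genes 10 fell and 3 rose (14 and 4 adjusted over the list alone), with the cytokine gene LTB (-0.82 ± 0.07) and the caspase inhibitor gene BIRC3 (-0.71 ± 0.07) lowest. With the slide as a block 3 NF-kB target genes fell, and IFI44L (adjusted p = 0.14) and PRF1 (0.069) did not pass.

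**Figure D2:**
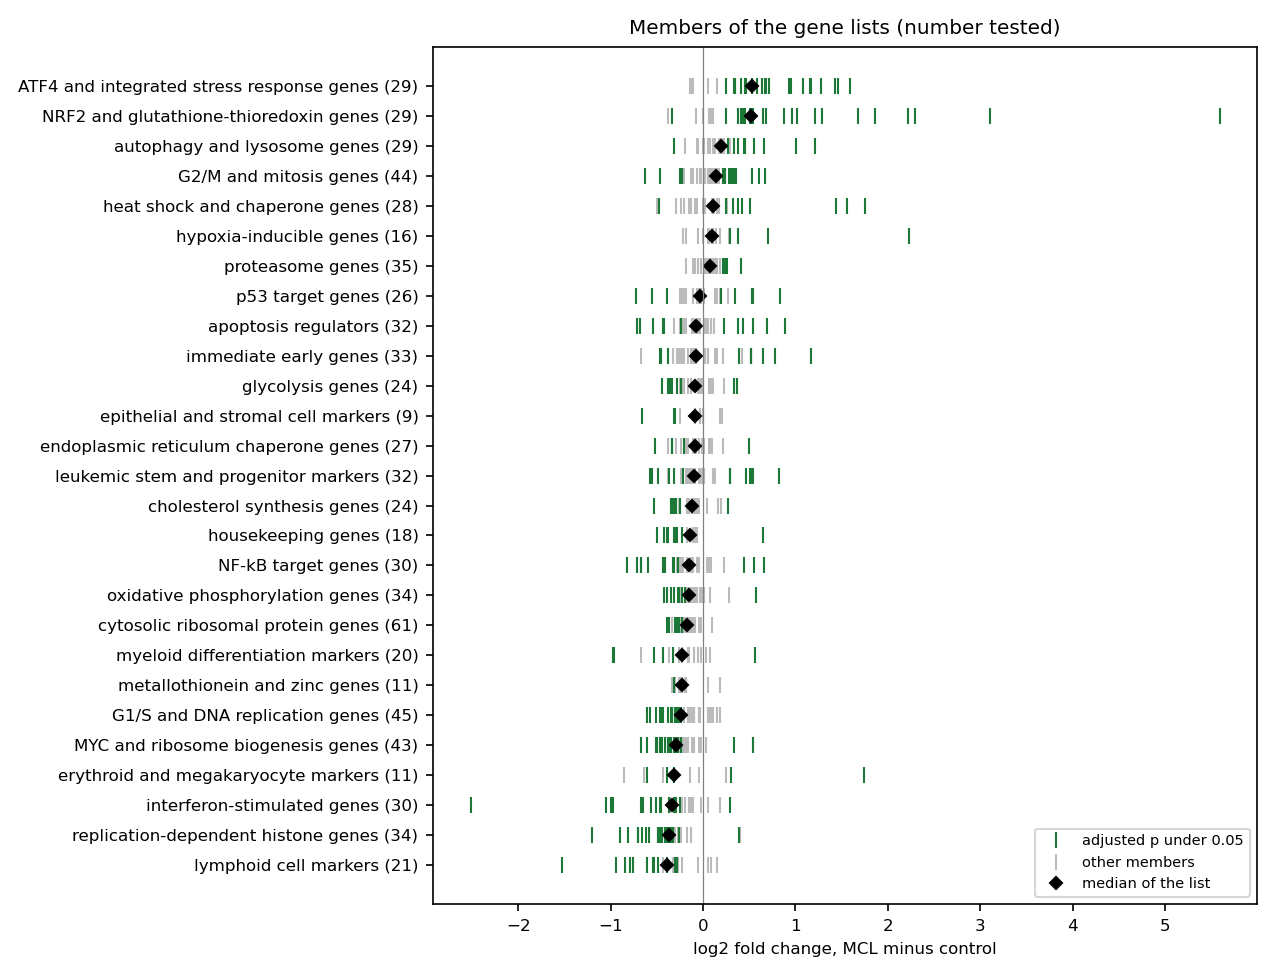
Log2 fold change, MCL minus control, of each tested member of the 27 gene lists (x axis), with the lists sorted by their median (y axis, number of tested members in brackets); green ticks are members past an adjusted p of 0.05, grey ticks the others, and diamonds the medians. The medians run from -0.39 for lymphoid cell markers to 0.54 for the ATF4 list.

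Differentiation and cell death genes went both ways. Of 32 leukemic stem and progenitor markers 8 rose and 6 fell (8 and 9 adjusted over the list alone), with the interleukin-3 receptor subunit IL3RA higher (0.82 ± 0.07, SE) and ID1 lower (-0.57 ± 0.08), and camera gave an adjusted p of 0.84. Of 20 myeloid differentiation markers 5 fell and 1 rose (the same when adjusted over the list alone), with the surface antigen CD33 (-0.97 ± 0.08), ITGAM (-0.53 ± 0.07) and the transcription factor SPI1 (-0.43 ± 0.08) lower and the granule protease CTSG higher (0.56 ± 0.08, camera adjusted p = 0.083). Of 32 apoptosis regulators 6 rose and 6 fell (6 and 8 adjusted over the list alone), with the pro-apoptotic genes HRK (0.89 ± 0.11) and BMF (0.69 ± 0.10) higher and BCL2L11 lower (-0.68 ± 0.06). Of 26 p53 target genes 5 rose and 3 fell (the same when adjusted over the list alone), with the cell cycle inhibitor CDKN1A higher (0.84 ± 0.08) and ZMAT3 lower (-0.73 ± 0.11). Of 33 immediate early genes 7 rose and 3 fell (7 and 4 adjusted over the list alone), led by ATF3 (1.17 ± 0.12), FOSL1 (0.78 ± 0.11) and FOS (0.66 ± 0.13). The last 3 lists had camera adjusted p values of 0.83, 0.40 and 0.42. The p53 and immediate early lists had negative medians (-0.03 and -0.08), positive means (0.01 and 0.03) and an upward direction in camera. The stem and progenitor list had a negative median (-0.10) and mean (-0.01) with an upward direction. In limma with the slide as a block 2 stem and progenitor markers rose and 1 fell, 1 myeloid marker fell, 2 apoptosis regulators rose and 2 fell, and 1 p53 target and 1 immediate early gene rose. ID1 (adjusted p = 0.066), ITGAM (0.071), SPI1 (0.14), CTSG (0.080), ZMAT3 (0.072), FOSL1 (0.066) and FOS (0.14) did not pass with that block.

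Of 27 endoplasmic reticulum chaperone genes 5 fell and 1 rose (3 and 1 adjusted over the list alone), with the chaperone HSPA5 lower (-0.52 ± 0.08, SE) and HERPUD1 higher (0.50 ± 0.10), and the median, -0.09, was 0.01 after quantile normalization. Of 24 cholesterol synthesis genes 7 fell and 1 rose (the same when adjusted over the list alone), with STARD4 lowest (-0.53 ± 0.07). Of 24 glycolysis genes 6 fell and 2 rose (9 and 3 adjusted over the list alone), with GPI (-0.45 ± 0.11) lower and PFKM (0.37 ± 0.09) higher. Of 34 oxidative phosphorylation genes 8 fell and 1 rose (the same when adjusted over the list alone), with the succinate dehydrogenase subunits SDHA lower (-0.42 ± 0.06) and SDHC higher (0.58 ± 0.16). Of 11 metallothionein and zinc genes 1 fell, MT1A (-0.31 ± 0.07, 1 adjusted over the list alone). Camera gave adjusted p values of 0.30, 0.076, 0.54, 0.051 and 0.17 for these 5 lists. With the slide as a block the oxidative phosphorylation list passed (camera adjusted p = 0.029). With an estimated correlation neither it (adjusted p = 0.35) nor the cholesterol list (0.24) passed. Within slide 1 the medians of these 2 lists were -0.16 and -0.15. The oxidative phosphorylation median was -0.15 over all 6 arrays, but -0.032 after quantile normalization and in the authors' value table, and -0.069 with normexp. Of 18 housekeeping genes 8 fell and 1 rose, ALAS1 (0.65 ± 0.08), the same counts as when adjusted over the list alone. This list passed in camera (adjusted p = 0.035, and 0.041 with the slide as a block), but not with an estimated correlation (adjusted p = 0.24), after quantile normalization (0.30), in the authors' value table (0.29), with normexp (0.25) or without control replicate 2 (0.055), control replicate 3 (0.051) or MCL replicate 1 (0.077). Of 11 erythroid and megakaryocyte markers 2 rose and 3 fell (2 and 5 adjusted over the list alone), with HBD higher and VWF lower (-0.61 ± 0.10, camera adjusted p = 0.82). Of 9 epithelial and stromal markers 3 fell (3 adjusted over the list alone), with PECAM1 lowest (-0.66 ± 0.07, camera adjusted p = 0.54). In limma with the slide as a block no endoplasmic reticulum chaperone, glycolysis, oxidative phosphorylation or metallothionein gene passed. With that block 1 gene each fell in the cholesterol and the epithelial and stromal lists, and 1 each rose in the housekeeping and the erythroid lists. HSPA5 (adjusted p = 0.069), HERPUD1 (0.18), GPI (0.066), PFKM (0.087), SDHA (0.057), SDHC (0.14), MT1A (0.25) and VWF (0.10) did not pass.

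Of the genes chosen by name in advance, NFKBIA, the inhibitor of NF-kB, fell by 0.59 ± 0.07 on the log2 scale (SE, limma adjusted p = 0.0022), with an adjusted p of 0.044 with the slide as a block and 0.055 within slide 1. MYC fell by 0.45 ± 0.07 on its brightest probe (SE, limma adjusted p = 0.0071), while its other 2 kept probes were not called, and the 3 probes ran from -0.45 to -0.17. On the brightest probe MYC did not pass with the slide as a block (0.11), within slide 1 (0.071) or with normexp (0.060). The stem cell antigen CD34 (-0.22 ± 0.07, SE, limma adjusted p = 0.060) and the anti-apoptotic gene MCL1, whose symbol only resembles the agent's name (-0.04 ± 0.07, adjusted p = 0.74), did not pass.

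The arrays of one group resembled each other more than those of the other group. Across the 26839 kept probes, which are not independent replicates, Pearson r was 0.995 to 0.997 between control arrays, 0.995 to 0.996 between MCL arrays and 0.988 to 0.992 between groups. The first principal component held 53.6% of the variance and separated the groups. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

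**Figure D3:**
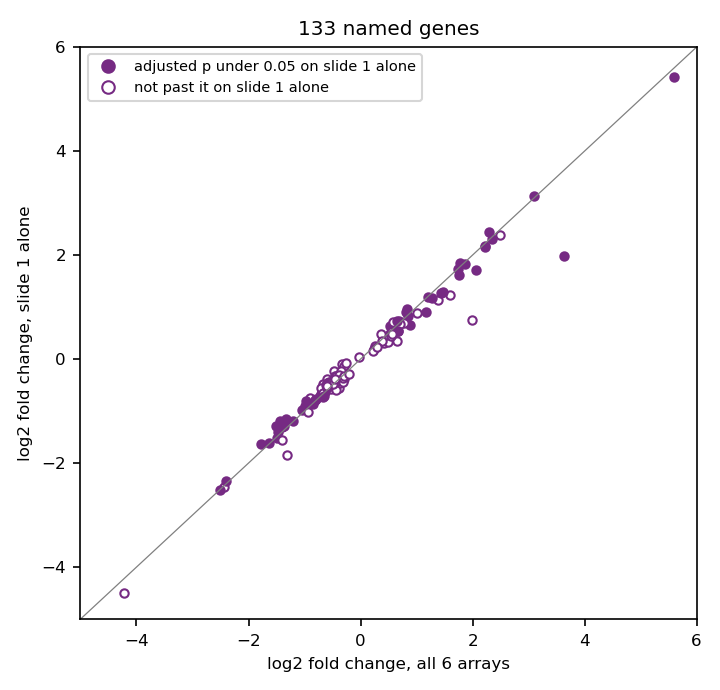
Log2 fold change of the 133 named genes on slide 1 alone, MCL replicate 1 against 3 control arrays (y axis), against that over all 6 arrays (x axis), with the line of equal values. Filled circles mark the genes with an adjusted p under 0.05 on slide 1 alone, where the spread comes from the control arrays only. Of the 133 genes 132 have the same sign in both, but the arrays of slide 1 are also part of the values on the x axis.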

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

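No alternative was chosen after the results were seen. Of 128 named genes past the threshold, 125 kept their direction under all alternatives run, and of 2552 alternative values 2156 also stayed past the threshold, 393 did not and 3 changed sign. Most of these genes were chosen for their calls in the main fit, and every alternative uses the same arrays or some of them. A kept direction was thus largely fixed in advance. Over all 3494 called genes, 120 had the opposite sign with normexp, 23 with the mean of a gene's probes and 2 with no filter on dim probes. The 3 named genes were under normexp background correction, with log2 changes of -0.14 for PPP1R36 (adjusted p = 0.81), -0.0897 for AMBP (0.89) and -0.12 for EGR1 (0.81), and the cause was not tested. The called counts were lowest within slide 1, which leaves 4 arrays (223 higher and 236 lower), and with the slide as a fixed block, which leaves 1 MCL array beside the controls (294 and 294). With the slide as a random block they were 1613 and 2710, at an estimated correlation within a slide of -0.12. A negative value treats arrays of one slide as less alike than others, so that fit does not guard against a slide difference. Normexp gave 367 higher, 582 lower and 69 at least 2-fold, and no filter on dim probes gave 682 and 951 among 18837 genes, for causes that were not tested. A threshold of 0.01 gave 485 and 651 by construction. Leaving out 1 array gave 817 to 1003 higher, 1163 to 1835 lower and 133 to 200 at least 2-fold. The counts fell by over 1.5 times without control replicate 1 (835 and 1318) and control replicate 3 (817 and 1163), and, for the lower genes, without control replicate 2 (1345). A total of 12 to 17 lists passed in camera under the other settings, 13 to 15 when 1 array was left out, 0 with an estimated correlation, and 19 in fry, against 14. The estimated correlation of the autophagy and lysosome list, 0.0069, was below the preset 0.01, yet its unadjusted camera p rose from 1.4e-06 to 0.0075. Losing a call in that setting is thus not by itself a sign of a higher correlation within a list. The NF-kB list had adjusted p between 0.023 and 0.050 under 10 of the alternatives that kept camera's preset correlation. The erythroid and megakaryocyte list went down in camera (adjusted p = 0.82) and up in fry (adjusted p = 0.017). Same-numbered control and MCL arrays share only a number: their deviations correlated at 0.08, 0.04 and 0.05, and the replicate block gave 1147 higher and 1841 lower genes and 14 lists. Dim signal limits the one-sided genes, since only arrays with a probe above background measure it.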

Other observations

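The gene families in the next paragraph, the splits of the samples for gene counts, the slide tests for the NRF2, ATF4 and lymphoid lists and the test of a smaller lymphoid share were tests chosen after the results they concern were seen. The other tests were chosen before.

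A total of 6 gene families outside the fixed lists were tested after their members' values were seen, so their p-values are not independent evidence. Of 18 tested MHC class I and antigen processing genes 11 fell and none rose in limma (14 and none adjusted over the list alone), led by the immunoproteasome subunits PSMB9 (-1.15 ± 0.07, SE) and PSMB8 (-0.98 ± 0.06) and the peptide transporter TAP1 (-0.78 ± 0.06). Camera's adjusted p was 8.5e-06, with adjusted p = 0.18 with an estimated correlation and 9.5e-08 with the slide as a block. All 5 tested GIMAP genes, which encode GTPases of immune cells, fell (5 adjusted over the list alone), with GIMAP6 at -1.05 ± 0.10 and GIMAP7 at -0.89 ± 0.06, and passed in camera with the preset (5.4e-05) and with an estimated correlation (adjusted p = 0.036). All 6 tested butyrophilin genes fell (6 adjusted over the list alone), BTN3A1 (-1.11 ± 0.08) and BTN3A3 (-1.08 ± 0.11) most, with camera adjusted p = 0.00011 and adjusted p = 0.056 with an estimated correlation. Of 5 Ikaros family genes IKZF1, IKZF2 and IKZF3 fell (3 adjusted over the list alone, camera adjusted p = 0.0030, adjusted p = 0.089 with an estimated correlation). Of 9 MHC class II genes 2 fell, HLA-DOB and CIITA (2 adjusted over the list alone, camera adjusted p = 0.066). Of 402 zinc finger genes with a ZNF symbol 51 rose and 12 fell (27 and 4 adjusted over the list alone, camera adjusted p = 0.00032, adjusted p = 0.036 with an estimated correlation), but their median was only 0.03 and turned to -0.03 with normexp. In limma with the slide as a block 4 MHC class I, 5 GIMAP, 3 butyrophilin and 2 Ikaros family genes fell, no MHC class II gene passed, and 2 zinc finger genes rose and none fell. BTN2A3P (adjusted p = 0.0504), BTN2A2 (0.12), BTN2A1 (0.13), IKZF1 (0.16), HLA-DOB (0.29) and CIITA (0.17) lost their calls. Camera with that block gave adjusted p = 3.9e-06 for the GIMAP and the butyrophilin genes, 0.0061 for the Ikaros family, 0.20 for MHC class II and 0.00018 for the zinc finger genes.

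The 6 arrays can be split 3 against 3 in 10 ways, which are too few for a share under 0.05. The real split gave 3494 genes past the limma threshold and 161 of them at least 2-fold, and 1 of the 10 splits, the real one, gave as many in each case. The highest other split gave 0 genes in limma, with 142 to 366 genes at an unadjusted p under 0.05 in the other splits against 5528. Every other split mixes control and MCL arrays on each side, so a difference between the groups adds to the spread within the sides. That lowers the gene counts of these splits in advance. The counts therefore do not measure what chance would give, and no conclusion is drawn from them. In 2 of the 10 splits camera with its preset correlation gave 14 lists, the real one and control replicates 1 and 2 with MCL replicate 1 against the rest. The remaining splits gave 2 to 13 lists, although no gene passed in them. Camera with its preset correlation thus passed lists in these arrays also where each side mixed the groups. The count of 14 lists therefore does not set the real split apart. A total of 6406 genes (47.5% of those tested) had all MCL values on one side of all control values, where 10% is the mean over the 10 splits. Genes do not vary independently, and a difference between the slides can add to this share. The share therefore does not test chance, and no conclusion is drawn from it.

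The NRF2 and ATF4 lists rose in camera with its preset correlation, but neither passed with an estimated correlation (adjusted p = 0.068). A difference between the slides was set against the 3 control arrays that share a slide with MCL replicate 1: relative to all genes the medians of both lists there were 0.53 to 0.58 on the log2 scale, which argues against the slide as the whole cause. The scaling or background method is argued against by medians of 0.62 to 0.66, again relative to all genes, under quantile normalization, normexp and the authors' value table. Not set against all genes, these medians were 0.54 to 0.64. A signal-dependent trend is argued against by excesses of 0.59 and 0.61 over random lists of like signal. A response to MCL may thus be a candidate explanation, as a hypothesis found and tested on these data.

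Several lists of bright genes fell, and the median change over all genes also varied with signal, from -0.21 in the dimmest of 10 equal groups of genes to -0.01 in the fourth and -0.12 in the brightest. The ribosomal protein and housekeeping medians lay at -0.018 and -0.028 from the middle of 10000 random lists matched on signal, inside their central range, and neither list passed after quantile normalization (adjusted p = 0.085 and 0.30). The random lists were drawn from all tested genes, the members of the list included, which moves their middle towards the list. The fall of the ribosomal protein and housekeeping lists may be part of this trend, but the comparison leans towards that outcome. The ribosome biogenesis and histone medians lay at -0.21 and -0.30 from that middle, outside the range, and passed after quantile normalization (adjusted p = 1.6e-05 and 6.7e-07), which argues against the trend as the whole cause. With an estimated correlation neither list passed (adjusted p = 0.33 and 0.47). The histone fall also varied with the control array: relative to all genes, the median for MCL replicate 1 was -0.16, -0.42 and -0.18 against control replicates 1 to 3. In the real split the histone median lay at -0.30 from that of all genes, and in splits that mix the groups at up to 0.22 either way.

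The lymphoid marker list fell in camera with its preset correlation, but did not pass with an estimated correlation (adjusted p = 0.19). A difference between the slides is argued against by medians of -0.24 to -0.38 relative to all genes, for MCL replicate 1 against the 3 control arrays of its slide. A smaller share of lymphoid cells in the MCL samples would lower all members alike, and the SD of their changes, 0.39, was 4.03 times the median SE, with CD3D lower (-0.79 ± 0.06) and CD7 at 0.09 ± 0.10. The samples are of KG1a cells, an established line, so a share of lymphoid cells would presume other cells in the cultures. The line may itself express some members, at differing levels, and CD3D stood at 3.63 in control. The spread of the changes therefore does not separate a smaller share from a response of the line. Of the 28 listed markers 7 had no probe that passed the filter and were not tested (BLK, CD79B, CD8B, GNLY, IL7R, KLRD1 and MS4A1).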
